A study of Mus musculus with 19 samples.

How the data were processed

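Gene expression was measured on 19 Affymetrix mouse expression arrays, 1 per RNA sample, each hybridised with biotin-labelled cRNA made by in vitro transcription of total RNA from wild-type ICR mouse embryos. Tissue was dissected by hand in buffer, kept in a stabilising solution and extracted on columns. The lens series holds lens of stages E10.5, E11.5 and E12.5 (embryonic days, the day of the vaginal plug counted as E0.5; 3 arrays per stage) and 4 arrays of whole embryonic body from E10.5 to E12.5. The tooth series holds molar tooth germ at E13.5 (3 arrays) and 3 arrays of whole body from E11.5 to E13.5. The labels do not say whether replicates of a group are separate litters, separate pools or repeat hybridisations, so every p-value here measures only the spread between these arrays, and the number of arrays limits the precision.

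The values deposited by the authors are intensity values, 1 per probe set (a group of short probes for 1 transcript) and array. Per the labels they come from RMA, which corrects background, brings the arrays to a common distribution and sums the probes of a set, and version 0.7 of a package named affy is listed, with no role or order stated for it. The intensity values are on a linear scale from 5.4 to 25043.5, with array medians over all probe sets from 42.5 to 46.5, and log2 was taken before any test. No pair of arrays shared more than 2.04% of its values exactly, so no array appears more than once among the 19. No further normalization was applied. There was no column of values that was left unused.

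Of 45101 probe sets, 34945 name 1 gene in the platform annotation of 2016, 932 name several genes, 9160 name none and 64 are controls. Symbols were looked up by Entrez ID in the RefSeq annotation of assembly GRCm38.p6, where 34741 probe sets matched. A gene is represented by the probe set that names only that gene and has the highest mean over the 19 arrays, which leaves 18193 genes. A gene was tested where its probe set exceeded the median of all values (44.1, or 5.46 on the log2 scale) on at least 3 arrays, which leaves 13320 genes. For comparison, 27 control probe sets with no target in the samples had a 95th percentile of 4.71 on the log2 scale.

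The tests were limma's (limma 3.58.1, R 4.3.3): a linear model with 1 mean per group over all 19 arrays, moderated tests of each contrast, and Benjamini-Hochberg adjusted p-values over the 13320 genes, called at an adjusted p under 0.05. All tests were two-sided. Differences are given on the log2 scale with the standard error (SE) of the model; levels are given with the standard deviation (SD) between arrays. The 9 contrasts were lens at each stage minus whole body of the lens series, the later minus the earlier lens stage for each pair of stages, tooth germ minus whole body of the tooth series, the lens difference at E12.5 minus the tooth difference, and the tooth-series bodies minus the lens-series bodies. The 3 stages share the same 4 body arrays, so the overlap of their calls was also counted with split controls and in simulated unchanged arrays.

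Groups, contrasts, the filter, the probe set rule, the rule for named genes, the alternatives listed as planned and 30 gene lists were fixed before the data were examined. The lists are lens crystallins, lens transcription factors, lens fibre membrane and cytoskeleton, cataract-linked genes other than crystallins, neural retina progenitors, pigment epithelium and melanocytes, mesenchyme and fibroblasts, surface ectoderm and epithelium, erythroid cells, endothelium, macrophages, skeletal and heart muscle, liver, neurons, cartilage, Hox genes, dental epithelium, dental mesenchyme, tooth agenesis-linked genes, cell division, cell cycle exit, FGF, BMP, Wnt and Notch signalling, basement membrane, immediate early and heat shock genes, glycolysis and hypoxia, cytosolic ribosomal proteins, and sex chromosome genes. Some genes stand in more than 1 list: 7 are shared by the fibre and cataract lists and 5 by the transcription factor and cataract lists, and the tooth agenesis list shares genes with both dental lists. Genes are named by a rule: the 10 largest rises and 10 largest falls per comparison among called genes whose groups do not overlap, up to 4 called members per list (2 where none is called), members that oppose their list, and 17 genes always named. Values of other genes are given where a set of arrays stands apart, and these were chosen after the values were seen.

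Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with a correlation estimated from the arrays. The test fry asks whether the genes of a list move, on balance, one way; neither it nor its mixed form compares a list with other genes. Counts of called members are also given adjusted over the list alone. For lens against body at E12.5 the list calls that held with the estimated correlation were lens transcription factors, fibre, cataract, basement membrane, cell division, mesenchyme, surface ectoderm, muscle, liver, neurons, cartilage, Hox genes, dental epithelium and dental mesenchyme; crystallins, erythroid cells and macrophages did not hold. For other comparisons the second value stands beside the first where it ends a call.

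Alternatives were other filters and probe set rules, repeated normalization, array centring, another variance model, array weights, stricter thresholds, other choices of control arrays, the groups compared alone, a replicate block, and each array left out in turn. Chosen after the data were seen were the division of the lens series by the bacterial hybridisation controls (6 arrays with high and 7 with low signal, parted at 9.93 on the log2 scale), used as a block and as separate subsets, and fits on the arrays of 1 series alone. Arrays with the same replicate number had a median correlation of gene residuals of -0.05 against 0.03 for other pairs. In the lens series the median was 0.33 for arrays of the same bacterial control set (25 of 31 pairs above 0.1) and -0.31 for arrays of different sets. The replicate numbers were not taken as pairing, except for E12.5 against E11.5 lens, where the same-numbered arrays correlated. There the value with a replicate block is printed beside the result. Those same-numbered arrays also share a bacterial control set, so number and set cannot be told apart as the source of the correlation. The decision for the block followed a fixed rule, but the counts with the block had been seen by then. The method was tested on simulated data in which 50 genes per step were raised or lowered by 1.5, 2, 4 or 8-fold: for E12.5 lens against body it called 30%, 88%, 100% and 100% of them, and 6 unchanged genes. For the lens minus tooth contrast it called 4%, 42%, 98% and 100%, and 7 unchanged genes. The simulated noise was independent between arrays and genes, with the same spread for a gene in all groups. The real residuals were correlated, so these shares and false calls need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.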

Results

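Transcript levels were measured in the mouse lens at 3 stages, in the molar tooth germ at 1 stage and in whole embryonic bodies. The lens series holds lens of stages E10.5, E11.5 and E12.5 (n = 3 arrays each) and whole body from E10.5 to E12.5 (n = 4). The tooth series holds tooth germ at E13.5 (n = 3) and whole body from E11.5 to E13.5 (n = 3). E10.5 lens is the time when the lens pit closes to a vesicle, and by E12.5 the cells at the back of the vesicle lengthen into primary fibres. The stated purpose of the series was to find genes enriched in a tissue over the body and to rank genes for cataract and tooth disorders. Signals ran from 5.4 to 25043.5 on the linear scale, and the number of arrays limits the precision. Correlations between arrays of a group lay between 0.946 and 0.994. Levels below are log2 signals with the SD between arrays, and differences are log2 with the SE of the fit. Control probe sets with no target had a 95th percentile of 4.71, and 12 was set as the level above which a signal counts as near the ceiling; differences that start below the first or end above the second are uncertain in size. Gene positions refer to the assembly GRCm38.p6.

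The first question was which genes the lens expresses above the body. Cryaa (Entrez gene 12954; chromosome 17, 31677931 to 31681730), which encodes alpha A-crystallin, a small heat shock protein that makes up much of the lens cytoplasm, stood at 13.05 ± 0.95 in E10.5 lens, 14.15 ± 0.22 at E11.5 and 14.39 ± 0.05 at E12.5 (SD, n = 3 each), against 5.02 ± 0.32 in the body (n = 4). Its difference from the body was 8.04 ± 0.30, 9.13 ± 0.30 and 9.37 ± 0.30 (SE) at the 3 stages, with an adjusted p of 1.5e-14 at E12.5. Pax6 (Entrez gene 18508; chromosome 2, 105668896 to 105698410), the transcription factor that specifies eye tissue, was at 11.91 ± 0.16, 11.54 ± 0.28 and 11.29 ± 0.22 in the lens and 7.36 ± 0.15 in the body. Prox1 (Entrez gene 19130; chromosome 1, 190118035 to 190170827), which lens fibre cells need in order to lengthen, exceeded the body by 4.23 ± 0.18, 5.14 ± 0.18 and 5.26 ± 0.18. Foxe3 (Entrez gene 30923; chromosome 4, 114924443 to 114926067), a factor of the lens epithelium, exceeded it by 4.18 ± 0.30, 4.70 ± 0.30 and 4.08 ± 0.30. In each of these 12 comparisons every lens array lay above every body array.

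**Figure D1:**
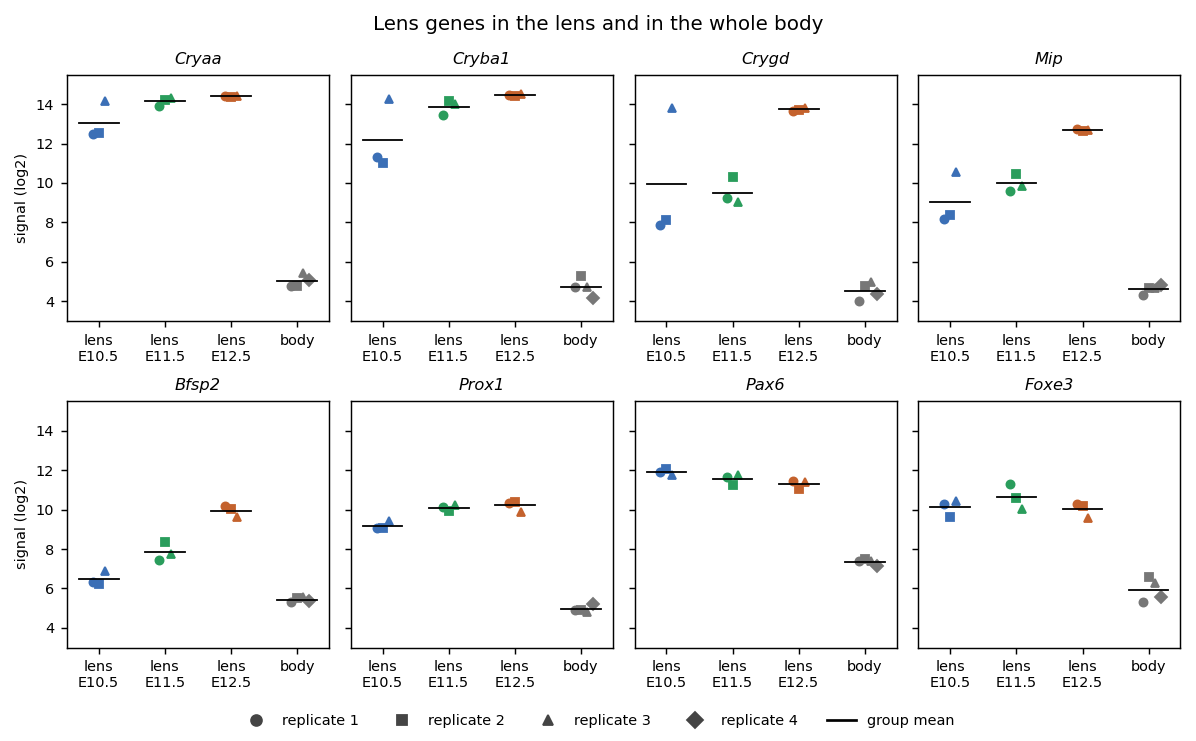
Signal (log2) on each array for Cryaa, Cryba1, Crygd, Mip, Bfsp2, Prox1, Pax6 and Foxe3 in E10.5, E11.5 and E12.5 lens (n = 3 arrays each) and whole body (n = 4); points are arrays and lines are group means. Cryaa stood at 13.05, 14.15 and 14.39 in the lens and 5.02 in the body.

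Among lens crystallins, the structural proteins of the lens, 10 of 14 were higher than in the body at E10.5, 12 at E11.5 and 14 at E12.5, with none lower (13, 13 and 14 when adjusted over the list alone). Their median difference was 4.52, 5.25 and 8.71. The list was called by camera at each stage (adjusted p = 2.5e-13 at E12.5), but adjusted p = 0.116, 0.0835 and 0.0501 with an estimated correlation. At E10.5, replicate 3 carried far more crystallin signal than the other arrays, for example 13.46 against a mean of 3.96 for Crygb, which stood at 3.58 in the body. Without replicate 3, 10 of the 14 were higher at E10.5 (10 adjusted over the list alone) and the median was 3.11. At E12.5 the gamma crystallins Cryga and Crygb exceeded the body by 9.63 ± 1.66 and 9.55 ± 1.51, and Cryba1, a beta crystallin, by 9.74 ± 0.76. Their lens levels (13.94, 13.13 and 14.45) lay near the ceiling and their body levels (4.31, 3.58 and 4.72) at background, so the sizes of these differences are uncertain.

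Of 14 lens transcription factors, 11 were higher at each stage and 1, 3 and 3 lower (the same when adjusted over the list alone), with a median of 3.18, 3.22 and 3.15 (camera adjusted p = 7.8e-12, 6.6e-09 and 5.6e-08). Pitx3 and Maf, in which mutations cause cataract, exceeded the body by 4.21 ± 0.17 and 3.79 ± 0.14 at E12.5, and Sox1, an activator of gamma crystallin genes, by 4.34 ± 0.28. Sox2, which acts with Pax6 in the early placode, was lower at E12.5 (-1.98 ± 0.25), as were Meis1 (-0.96 ± 0.13) and Meis2 (-2.20 ± 0.32). At E10.5 Meis2 was lower by its main probe set (-1.73) and higher by another (2.03).

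Fibre membrane and cytoskeleton genes were higher for 9, 9 and 10 of 12 members, with 1, 2 and 1 lower (the same counts when adjusted over the list alone) and medians of 1.49, 2.14 and 4.43. The camera call had adjusted p = 0.138, 0.0732 and 0.0214 with an estimated correlation at the 3 stages. Mip, the water channel of fibre membranes, exceeded the body by 8.06 ± 0.38 at E12.5, and Gja3, a gap junction protein, by 8.33 ± 0.39. Cataract-linked genes other than crystallins, of which 12 also stand in the 2 lists before, were higher for 13, 18 and 18 of 26 members and lower for 2, 4 and 3 (14, 19 and 19 higher when adjusted over the list alone). Their median was 0.90, 1.19 and 2.09 (camera adjusted p = 3.4e-06, 3.7e-08 and 2.5e-09). Tdrd7, an RNA granule protein, was 5.25 ± 0.30 above the body at E12.5. Unc45b, a myosin chaperone, was below it (-2.87 ± 0.21).

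Basement membrane genes, which include the collagen IV chains of the lens capsule, were higher for 10, 11 and 11 of 14 members and lower for 1, 3 and 3 (adjusted over the list alone, 10, 11 and 11 higher and 2, 3 and 3 lower). The median was 1.10, 1.29 and 1.12 (camera adjusted p = 1.3e-05, 4.9e-06 and 3.1e-05). Col4a6 exceeded the body by 2.43 ± 0.18, 3.25 ± 0.18 and 4.03 ± 0.18, and Col4a5 by 2.54 ± 0.24, 3.18 ± 0.24 and 3.81 ± 0.24. Nid2, a linker protein of basement membranes, was lower (-1.20 ± 0.16 at E12.5).

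Genes outside these lists stood among the largest differences at E10.5; the genes named for the size of their change in any comparison had groups of arrays that did not overlap. Aldh1a1, a retinaldehyde dehydrogenase, exceeded the body by 6.90 ± 0.18, Trpm3, a cation channel whose gene hosts a lens-expressed microRNA, by 6.23 ± 0.20, and Csn3, kappa casein of milk, by 5.67 ± 0.28. Afp (Entrez gene 11576; chromosome 5, 90490714 to 90508907), the fetal serum protein made by liver and yolk sac, lay below the body (-9.91 ± 0.35, adjusted p = 7.1e-14), and Actc1, cardiac actin, lay below it too (-8.12 ± 0.20).

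Markers of other organs were lower in the lens. At E12.5 all 14 skeletal and heart muscle genes, all 10 liver genes and all 13 neuron genes were lower, with medians of -4.44, -4.47 and -4.61 (camera adjusted p = 3.0e-14, 2.2e-11 and 8.0e-15; the same counts when adjusted over the list alone). Cartilage genes were lower for 10 of 10 members (median -2.44), for example Col2a1, the main cartilage collagen, at -3.90 ± 0.30. Hox genes, which mark the trunk and limbs, were lower for 24 of 25 tested members (25 adjusted over the list alone; median -1.86), for example Hoxa10 at -3.68 ± 0.19. Mesenchyme and fibroblast genes were lower for 13 of 14 (median -2.47), for example Prrx1, a limb and facial mesenchyme factor, at -4.70 ± 0.21. Erythroid genes were lower for 6 of 7 (median -1.92, camera adjusted p = 0.00134, but adjusted p = 0.148 with an estimated correlation), for example Klf1 at -3.94 ± 0.22.

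Of 11 endothelial genes 3 were lower at E12.5, among them the junction gene Cldn5 (-1.05 ± 0.19), and the list was not called (median -0.21, adjusted p = 0.685). Of 11 macrophage genes 8 were higher and 2 lower at E10.5 (the same adjusted over the list alone; median 0.92, camera adjusted p = 0.0151, but adjusted p = 0.406 with an estimated correlation). Higher were, for example, Cx3cr1, the fractalkine receptor, by 1.44 ± 0.22 and Tyrobp, an adaptor protein of myeloid cells, by 1.36 ± 0.26, and the mannose receptor Mrc1 was lower (-1.59 ± 0.21). At E12.5 5 were higher and none lower, with a median of 0.48 (camera adjusted p = 0.0183, but adjusted p = 0.446 with an estimated correlation).

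**Figure D2:**
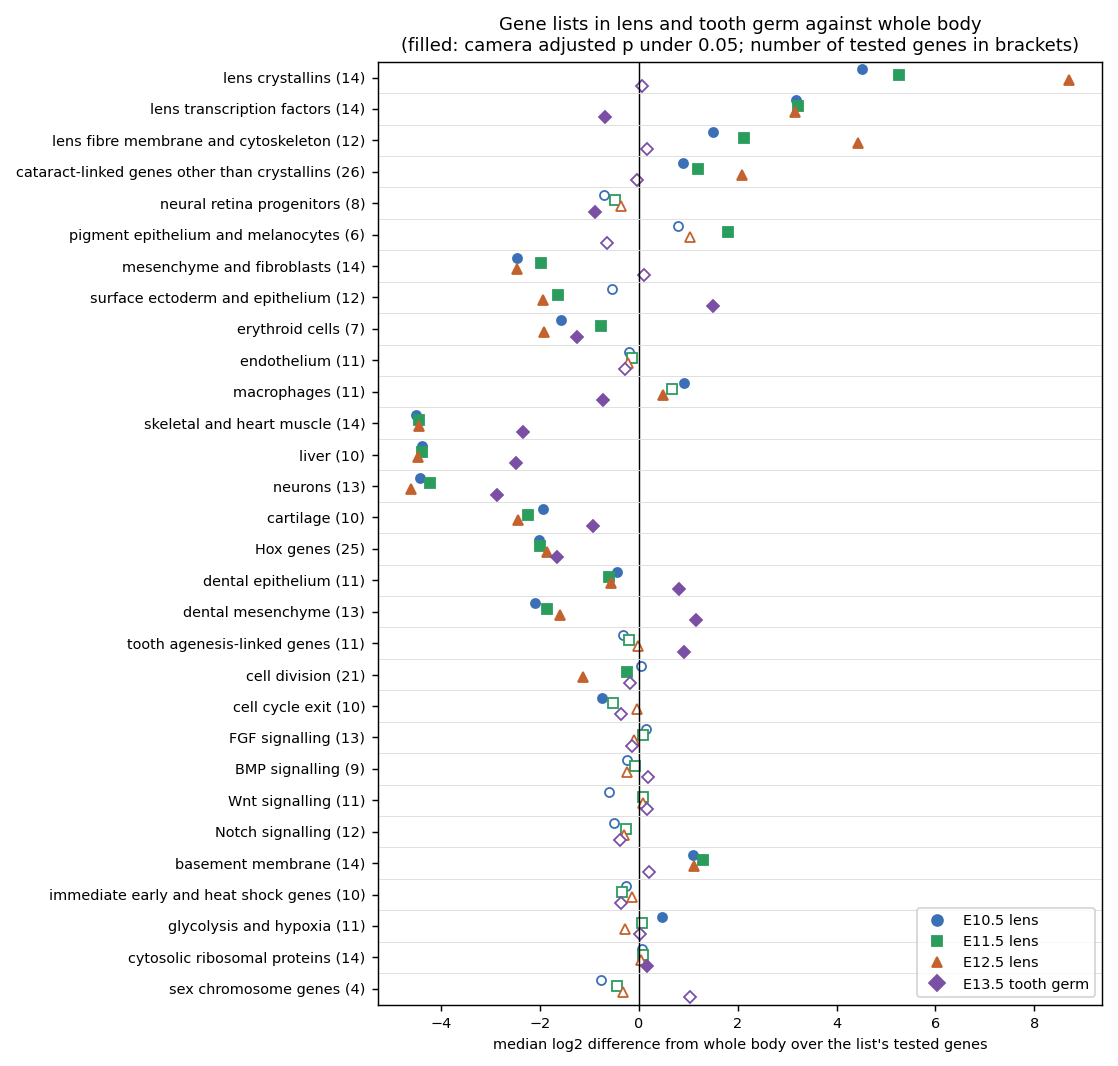
Median log2 difference from whole body of each of the 30 gene lists in E10.5, E11.5 and E12.5 lens and E13.5 tooth germ, with the number of tested genes in brackets; filled points are lists with a camera adjusted p under 0.05. Lens crystallins stood at 4.52, 5.25 and 8.71 in the lens and 0.07 in tooth germ.

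In all, 1797 genes were higher and 2548 lower in E10.5 lens than in the body, 1954 and 2965 at E11.5, and 2215 and 3559 at E12.5. At least 2-fold were 486 and 1347, 528 and 1405, and 763 and 1667 of these. The lens and body arrays did not overlap for 40.4%, 38.3% and 49.0% of genes, where chance gives 5.71%. Without E10.5 replicate 3 the counts at E10.5 were 1606 and 2413. The medians over the tested genes differed between lens and body arrays by -0.08, -0.13 and -0.14 on average and the median gene by -0.01, -0.03 and -0.05, and centring every array on its median changed the counts to 2378 higher and 2292 lower at E10.5, to 2768 and 2446 at E11.5 and to 3161 and 2876 at E12.5.

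Higher at all 3 stages were 1010 genes (296 at least 2-fold at each stage), and lower at all 3 were 1937 (1021). Independent lists of these sizes would share 43.8 and 152. Simulated arrays gave a median of 0 in each direction, but they hold no changed gene and so almost no calls. They cannot show what the shared body arrays add to the overlap. With the 4 body arrays split between E10.5 and E12.5, 769 or 683 genes were higher at both stages, against 1081 with all 4 arrays and 186, 167 and 299 for independent lists. Without E10.5 replicate 3 the count of genes higher at all 3 stages was 845, and within the arrays of high and of low bacterial control signal it was 512 and 834.

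The second question was how the lens changes with age. From E10.5 to E11.5 some genes of the surface ectoderm fell. Epcam (Entrez gene 17075; chromosome 17, 87635979 to 87651127), an adhesion molecule of simple epithelia, went from 10.13 ± 0.18 to 7.12 ± 0.17 (SD, n = 3 each; difference -3.00 ± 0.16, adjusted p = 1.1e-09), and then to 5.36 ± 0.18 at E12.5. The keratin Krt8 (-3.23 ± 0.22), the splicing regulator Esrp1 (-3.24 ± 0.24) and Dsp, a desmosome protein (-3.69 ± 0.23), fell as well. Csn3 (Entrez gene 12994; chromosome 5, 87925579 to 87932550) went from 10.82 ± 0.79 to 6.02 ± 0.31. In the surface ectoderm list 6 of 12 genes fell and none rose (6 when adjusted over the list alone; median -0.53, camera adjusted p = 2.2e-08), and against the body the list went from 5 higher and 6 lower at E10.5 to 1 higher and 10 lower at E12.5. Cdh1, E-cadherin, was the member that was still higher (2.98 ± 0.16).

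Among the rises from E10.5 to E11.5 were the extracellular matrix genes Col1a2 (2.31 ± 0.22) and Lum (1.90 ± 0.24) and the pigment cell gene Pmel (1.71 ± 0.17). The mesenchyme, pigment and erythroid lists had positive medians in this step and medians of -0.51, -1.16 and -0.74 in the next. Against the body the pigment list was higher at E11.5 (median 1.81, camera adjusted p = 0.0039, and 0.0192 with an estimated correlation). Tissue was dissected by hand, so lens cells and neighbouring cells carried along cannot be told apart here or for the surface ectoderm list. Of the mesenchyme list 4 of 14 rose (6 adjusted over the list alone; median 0.44, camera adjusted p = 7.2e-05, but adjusted p = 0.139 with an estimated correlation). Of the pigment list 2 of 6 rose (5 adjusted over the list alone; median 0.66, camera adjusted p = 4.5e-06), and at E12.5 Pmel had fallen again (-1.49 ± 0.17 from E11.5). Of 7 erythroid genes 2 rose (5 adjusted over the list alone; median 0.82, camera adjusted p = 1.8e-05, but adjusted p = 0.0934 with an estimated correlation). Of 14 crystallins none was called in this step (2 adjusted over the list alone; median 0.94, camera adjusted p = 0.0238, but adjusted p = 0.675 with an estimated correlation), and the list moved to a median of -0.97 among the arrays with low bacterial control signal, whose only E10.5 array is replicate 3. Without E10.5 replicate 3, Cryaa was 1.64 higher at E11.5 and Crybb1 4.42 higher, both called. The fibre gene Bfsp2 rose by 1.37 ± 0.23 and Prox1 by 0.91 ± 0.19; the latter call ended without E10.5 replicate 2 (0.85).

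In this step 203 genes rose and 365 fell (74 and 133 at least 2-fold). The groups did not overlap for 17.5% of genes, where chance gives 10%. Without E10.5 replicate 3 the counts were 342 and 408, without replicate 2 they were 71 and 136, and with the 6 arrays alone they were 9 and 47. The arrays of the lens series fall into a set with high and a set with low bacterial control signal. The high set holds 1 array each of E11.5 and E12.5 and the low set 1 of E10.5, and a lone array is assumed to vary like the other groups. With this set as a block 269 rose and 568 fell; within the high set the counts were 382 and 1091 and within the low set 51 and 71. With each array centred on its median 284 rose and 343 fell.

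From E11.5 to E12.5 most cell division genes and some pigment genes fell, and some fibre genes rose. Tmod1, which caps actin filaments in the fibre membrane skeleton, rose from 6.71 ± 0.59 to 9.64 ± 0.06 (SD, n = 3 each; 2.93 ± 0.24, adjusted p = 1.7e-06), Mip by 2.71 ± 0.40 and Bfsp2 (Entrez gene 107993; chromosome 9, 103424924 to 103480405), a beaded filament protein, by 2.08 ± 0.23. Of 12 fibre genes 5 rose and none fell (8 and 1 adjusted over the list alone; median 1.72, camera adjusted p = 2.2e-08, but adjusted p = 0.0689 with an estimated correlation). Of 14 crystallins Crygb, Crygf and Crygd rose, by 5.80 ± 1.62, 5.24 ± 1.21 and 4.21 ± 0.98 (9 adjusted over the list alone; median 1.99, camera adjusted p = 1.3e-06, but adjusted p = 0.386 with an estimated correlation). The call of Crygb ended without E11.5 replicate 1 or 3 or any 1 of the E12.5 arrays, with values from 4.59 to 5.87, and that of Crygd without E11.5 replicate 3 or E12.5 replicate 3 (3.98 and 4.18). Hsf4, a heat shock factor in which mutations cause cataract, rose by 1.59 ± 0.21. Gcg, the proglucagon gene, and Pla2g7, a secreted phospholipase, rose by 4.51 ± 0.50 and 4.60 ± 0.73.

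Of 21 cell division genes 20 fell between E11.5 and E12.5 and none rose (21 adjusted over the list alone; median -0.94, camera adjusted p = 3.3e-29, and 0.00288 with an estimated correlation). Birc5, a subunit of the chromosomal passenger complex (-1.11 ± 0.14), Rrm2, which makes deoxynucleotides (-1.09 ± 0.14), and Aurka, a spindle kinase (-1.10 ± 0.18), were among them. From E10.5 to E12.5 all 21 fell (median -1.32). Mki67 (Entrez gene 17345; chromosome 7, 135689784 to 135716450), a marker of cycling cells, stood at 11.37 ± 0.38, 10.67 ± 0.55 and 9.71 ± 0.63 in the lens at the 3 stages and at 11.38 ± 0.16 in the body. Of the 10 genes of the cell cycle exit list 4 rose and 2 fell over the same time (median 0.50, adjusted p = 0.392, not called). The CDK inhibitor Cdkn1c rose by 1.25 ± 0.17 and the pocket protein Rbl2 by 1.10 ± 0.23, and Gas1 fell by 1.40 ± 0.16.

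**Figure D3:**
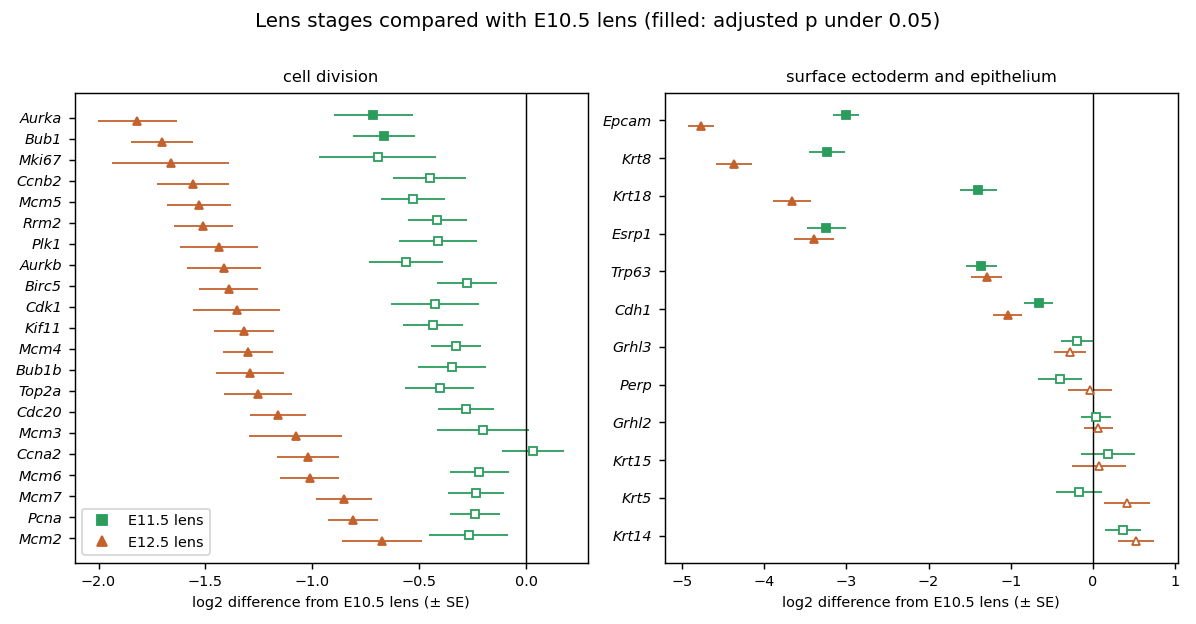
Log2 difference of E11.5 and E12.5 lens from E10.5 lens (n = 3 arrays each) for genes of the cell division and the surface ectoderm lists; bars are the SE of the fit and filled points have an adjusted p under 0.05. All 21 cell division genes lay below 0 at E12.5, with a median of -1.32.

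Other genes that fell from E11.5 to E12.5 were Tnc, the matrix protein tenascin C (-3.05 ± 0.26), Krt18 (-2.27 ± 0.23) and Otx2, a factor of the early optic vesicle (-2.07 ± 0.19). Of 6 pigment genes, Otx2 among them, 3 fell and none rose (4 adjusted over the list alone; median -1.16, camera adjusted p = 5.3e-05, and 0.00743 with an estimated correlation). Of 14 mesenchyme genes 5 fell and none rose (8 and 1 adjusted over the list alone; median -0.51, camera adjusted p = 0.000717, but adjusted p = 0.323 with an estimated correlation). Of 7 erythroid genes 2 fell (4 adjusted over the list alone; median -0.74, camera adjusted p = 0.00295, but adjusted p = 0.342 with an estimated correlation). In total 402 genes rose and 459 fell (199 and 85 at least 2-fold), with groups that did not overlap for 19.1% of genes. With the replicate block 370 rose and 431 fell, and Btg2, Dkk1, Smad6 and Aldoa were no longer called. With the 6 arrays alone the counts were 76 and 63, and without E12.5 replicate 3 they were 233 and 209. Within the high set of bacterial control signal, which holds 1 array of each stage, 372 rose and 71 fell, and within the low set 396 and 594. With each array centred on its median 507 rose and 447 fell.

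Over the whole time from E10.5 to E12.5, 1187 genes rose and 1759 fell (468 and 553 at least 2-fold; groups apart for 38.4% of genes, 10% by chance). Without E10.5 replicate 3 the counts were 1220 and 1731, and within the sets of high and low bacterial control signal 672 and 896, and 759 and 1079. With each array centred on its median 1543 rose and 1541 fell, and with quantile normalization 1403 and 1534. Of 14 crystallins 11 rose and none fell (12 adjusted over the list alone; median 3.79, camera adjusted p = 1.4e-06, but adjusted p = 0.448 with an estimated correlation), for example Crygn by 4.35 ± 0.88 and Cryba2 by 4.28 ± 0.88. In the low set, which holds replicate 3 as its only E10.5 array, that median was 0.20 and the list was not called. Cxcl14, a chemokine of epithelia (-5.53 ± 0.60), and Vcan, the proteoglycan versican (-4.79 ± 0.23), fell. Of 11 glycolysis and hypoxia genes 6 fell and 1 rose (7 and 1 adjusted over the list alone; median -0.62, camera adjusted p = 0.00425, but adjusted p = 0.0932 with an estimated correlation). Ldha, lactate dehydrogenase (-1.03 ± 0.11), and the oxygen sensor Egln3 (-1.48 ± 0.19) were among those that fell. Of 13 FGF signalling genes 2 rose and 6 fell (median -0.57, adjusted p = 0.230, not called): Fgfr3 rose by 2.98 ± 0.48, and the MAP kinase phosphatase Dusp4 fell by 2.35 ± 0.13.

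**Figure D4:**
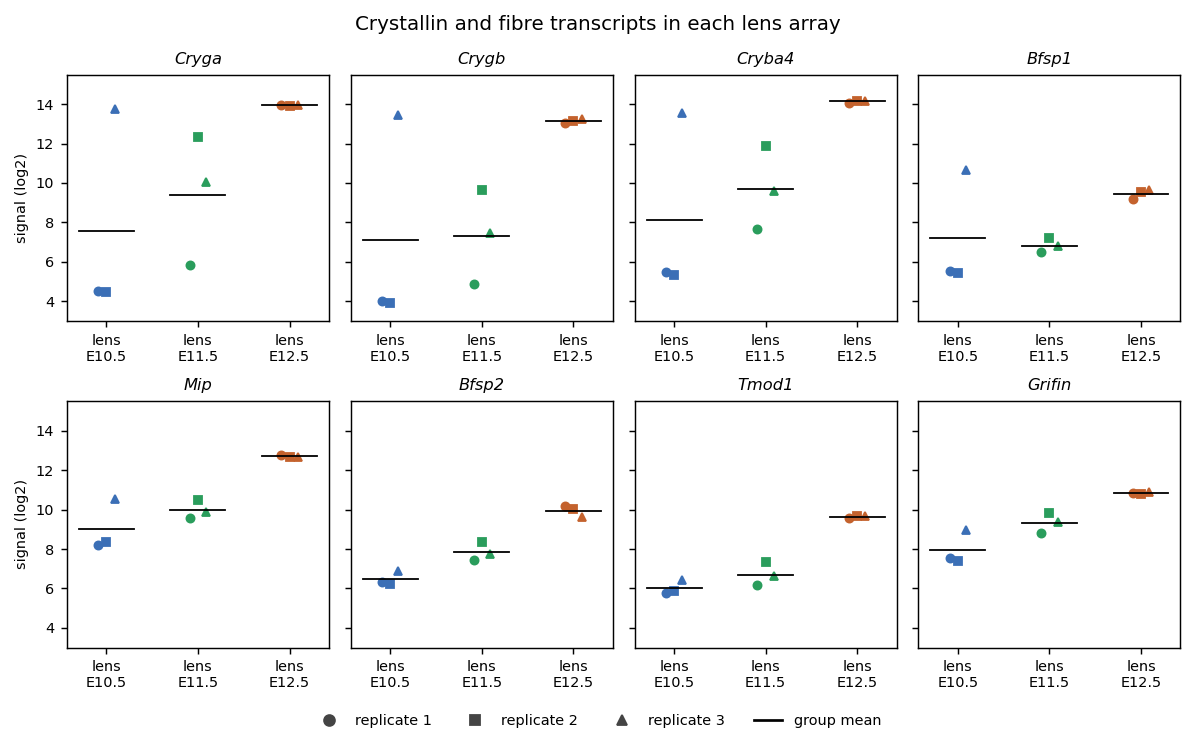
Signal (log2) of Cryga, Crygb, Cryba4, Bfsp1, Mip, Bfsp2, Tmod1 and Grifin on each lens array of stages E10.5, E11.5 and E12.5 (n = 3 each); points are arrays, with a symbol per replicate number. E10.5 replicate 3 read 13.46 for Crygb, where the other E10.5 arrays averaged 3.96, and 6.41 for Tmod1, where they averaged 5.82.

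The third question was which genes the tooth germ expresses above the body. Krt17 (Entrez gene 16667; chromosome 11, 100256215 to 100261029), a keratin of ectodermal appendages, stood at 9.19 ± 0.21 in tooth germ and 3.37 ± 0.08 in the body (SD, n = 3 each; 5.82 ± 0.17, adjusted p = 2.5e-14). The body level lies below the 4.71 of control probe sets with no target, so the size of that difference is uncertain. Lhx8 (Entrez gene 16875; chromosome 3, 154306288 to 154330560), a homeobox gene of oral mesenchyme, stood at 10.82 ± 0.08 against 7.86 ± 0.09, and Msx1 (Entrez gene 17701; chromosome 5, 37820491 to 37824585), in which mutations cause missing teeth, at 11.06 ± 0.08 against 8.55 ± 0.12. Of 13 dental mesenchyme genes 11 were higher and none lower (the same when adjusted over the list alone; median 1.15, camera adjusted p = 1.5e-07); Lhx6 was 2.49 ± 0.19 higher and Inhba, which encodes an activin subunit, 2.42 ± 0.13. Pax9, a factor without which molars do not form past the bud, differed by 0.35 ± 0.14 (adjusted p = 0.045), a call that ended in 9 alternatives (adjusted p from 0.052 to 0.54), and with all whole-body arrays as the control Barx1, a molar field gene, was at 0.15 and Bmp4 at 0.43, neither called, in place of 1.15 and 1.19.

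Dental epithelium genes were higher for 7 of 11 members and lower for 1, Bmp2 (adjusted over the list alone, 7 and 2; median 0.82, camera adjusted p = 0.00249). Sostdc1, a BMP and Wnt antagonist, was 3.55 ± 0.18 higher, and Shh was at -0.93 ± 0.38 (adjusted p = 0.053). Surface ectoderm genes were higher for 9 of 12 members and lower for none (9 adjusted over the list alone; median 1.51, camera adjusted p = 3.5e-08): the basal keratins Krt14 and Krt5 by 3.56 ± 0.22 and 2.98 ± 0.28, and Trp63, which maintains stratified epithelia, by 2.68 ± 0.19. Of 11 tooth agenesis-linked genes 8 were higher and 1 lower (9 and 1 adjusted over the list alone; median 0.91, camera adjusted p = 1.9e-04, and 0.0496 with an estimated correlation), for example Edaradd, the adaptor of the ectodysplasin receptor, by 2.52 ± 0.26; Axin2 was lower (-0.68 ± 0.21). Msx1, Pax9, Bmp4, Wnt10a and Wnt10b of this list also stand in the 2 dental lists, so these results share genes.

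**Figure D5:**
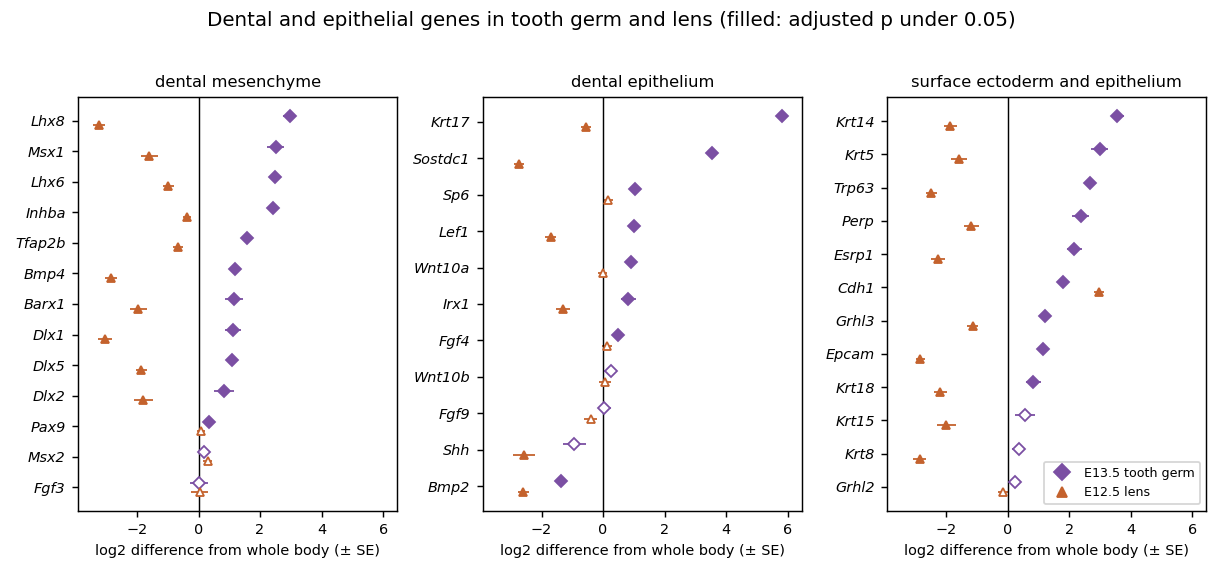
Log2 difference from whole body of E13.5 tooth germ (n = 3 arrays and 3 body arrays) and E12.5 lens (n = 3 and 4) for genes of the dental mesenchyme, dental epithelium and surface ectoderm lists; bars are the SE of the fit. Krt17 lay at 5.82 and Lhx8 at 2.96 in tooth germ.

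Neuron genes were lower in tooth germ for 13 of 13 members, muscle for 13 of 14, liver for 9 of 10 and Hox genes for 17 of 25 (medians -2.87, -2.34, -2.47 and -1.66), for example Nefl, a neurofilament protein, at -6.97 ± 0.25. Mesenchyme genes went both ways, 5 higher and 4 lower (median 0.11, mean -0.43, not called). Of 14 cytosolic ribosomal protein genes 6 were higher and none lower (median 0.17, camera adjusted p = 0.0137, but adjusted p = 0.185 with an estimated correlation), and the list moved to -0.08 with all whole-body arrays as the control. Of 14 crystallins 1 was lower, Cryab, a small heat shock protein also made in muscle and heart (-2.43 ± 0.23). Tooth germ replicate 3 read 8.88 for Cryba1, where the other tooth arrays averaged 4.85.

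In total 2214 genes were higher and 3370 lower in tooth germ (523 and 1386 at least 2-fold; groups apart for 56.1% of genes, 10% by chance). Without tooth replicate 3 the counts were 1910 and 3024. The medians over the tested genes differed by -0.15 between the groups, and centring each array on its median gave 3285 higher and 2724 lower. Of 1673 genes with at least 2 called probe sets, 385 (23.0%) had calls in opposite directions, against 4.37% to 5.63% in the comparisons of lens with body. In the tooth series the 5' to 3' signal ratio of Gapdh lay between 0.0590 and 0.142, against 0.964 to 1.07 in the lens series. It was 0.115 to 0.142 in tooth germ and 0.0590 to 0.0700 in the body, and that of actin 0.0302 to 0.0365 and 0.0450 to 0.0537. The mean bacterial control signal was 9.54 to 9.92 in tooth germ and 7.44 to 8.26 in the body. None of these 3 measures overlapped between the groups, so a difference in sample quality or hybridisation cannot be told apart from the tissue in this comparison.

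The fourth question was where the lens and the tooth germ differ in their enrichment over the body. Of the genes higher in E12.5 lens, 400 were also higher in tooth germ (368 for independent lists; odds ratio 1.13, Fisher's exact p = 0.0489), and 1436 were lower in both (900 for independent lists; odds ratio 2.74). Opposite calls were made for 950 genes, 473 higher in lens and lower in tooth and 477 the reverse. Independent lists would give 560 and 592 (odds ratios 0.769 and 0.715, Fisher's exact p = 2.4e-06 and 1.0e-09). Fisher's exact test takes genes as independent, which genes that move together are not, so its p-values do not measure the spread between arrays. Tested directly, 2564 genes were more enriched in the lens and 2714 in the tooth germ (1539 and 1603 at least 2-fold; 2425 and 2489 without tooth replicate 3). Of the 2564, 1339 were called higher in the lens and 1614 lower in tooth germ. Of 1713 genes with at least 2 called probe sets in this contrast, 194 (11.3%) had calls in opposite directions. The contrast includes tooth germ minus body, where sample quality or hybridisation cannot be told apart from the tissue. That limit also holds for the genes and lists of this contrast. Pax6 had a difference of 7.68 ± 0.50, since it was 3.93 ± 0.34 above the body in lens and below it in tooth germ (-3.76 ± 0.37). Sox1 and Prox1 differed by 7.29 ± 0.42 and 7.11 ± 0.26.

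Lens transcription factors were more enriched in the lens for 12 of 14 members (median 3.61, camera adjusted p = 9.3e-12) and cataract-linked genes for 17 of 26, with 3 the other way (median 2.11, adjusted p = 6.1e-08). In the other direction went dental mesenchyme (10 of 13, median -2.94, adjusted p = 1.5e-08), dental epithelium (8 of 11, median -1.23, adjusted p = 1.8e-05) and surface ectoderm (10 of 12, median -3.38, adjusted p = 1.5e-08; Cdh1 was more enriched in the lens, by 1.18 ± 0.24). These 5 calls held with an estimated correlation. Crystallins were more enriched in the lens for 14 of 14 members (median 8.38, camera adjusted p = 3.9e-10, but adjusted p = 0.0972 with an estimated correlation). Among single genes Postn, periostin, was at -6.46 ± 0.30 and Lhx8 at -6.20 ± 0.29. Against the tooth germ directly, without the body arrays, the counts were 4449 and 4405. Lens and tooth germ arrays belong to different series, and the bodies of these series alone gave 4238 and 4236. The direct counts thus cannot tell tissue from series.

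The control arrays were also compared with each other. Between the whole-body arrays of the tooth and lens series 4238 genes were higher and 4236 lower (1986 and 2051 at least 2-fold), and the groups did not overlap for 65.4% of genes, where chance gives 5.71%. Of 3877 genes with at least 2 called probe sets, 2064 (53.2%) had calls in opposite directions. Xist, the transcript that silences an X chromosome, was 7.16 ± 1.00 higher in the tooth-series bodies, and the G protein subunit Gnb2 (-5.60 ± 0.16) and the membrane glycoprotein Bsg (-5.54 ± 0.13) were lower. Each tissue was compared with the bodies of its own series.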

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

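The tests of explanations and of other splits of the arrays in this part were written down after the results they measure had been seen. For the lens RNA test of tooth germ replicate 3, the reading of the result was also changed after a first run: the first rule counted lens RNA as excluded by a slim margin, and the rule used here asks in addition that the Cryaa probe set respond in the whole-body arrays of the same series.

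The lens differed between stages, which is a difference of the same tissue-to-body contrast at different ages. From E10.5 to E11.5 203 genes rose and 365 fell, from E11.5 to E12.5 402 rose and 459 fell, and from E10.5 to E12.5 1187 rose and 1759 fell. From E10.5 to E12.5 the surface ectoderm list had a median of -0.66 and the cell division list of -1.32. For E11.5 against E10.5 the 10 splits of the 6 arrays are too few for a share under 0.05. The real split called 568 genes and the highest of the others 706, so 2 splits called as many. That other split follows the sets of high and low bacterial control signal, which points to a structure of the samples; with the set as a block 269 genes rose and 568 fell. For E12.5 against E11.5 the 10 splits are also too few: the real split called 861 genes and the highest of the others 250, and 1 split called as many. The 3 other splits that part the replicate numbers as the real split does called 0 genes, with limma at an adjusted p under 0.05. For E12.5 against E10.5 the splits are too few as well, with 2946 genes against 1 for the highest of the others.

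The enrichment over the body differed between lens and tooth germ, by a direct test of the difference. It was higher in lens for 2564 genes and lower for 2714, and the median difference was 3.61 for lens transcription factors, 2.11 for cataract-linked genes, -3.38 for surface ectoderm, -1.23 for dental epithelium and -2.94 for dental mesenchyme. Only the real assignment, 1 of 100, called as many as 5278 genes, and the highest of the other draws called 3004. For tooth germ against body the 10 splits are too few for a share under 0.05, with 5584 genes in the real split and 0 in the highest of the others. Sample quality or hybridisation cannot be told apart from the tissue in that comparison, which also enters the test of lens against tooth enrichment.

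For the lens against the body only the real split called as many genes. Splits and draws in this part treat the arrays as exchangeable, and the labels do not say whether replicates are separate litters. Chance between animals is therefore not excluded, and the 3 stages share the body arrays. The real split called 4345 genes at E10.5, 4919 at E11.5 and 5774 at E12.5, and the highest of the other splits 2393, 2663 and 3313 (1 of 35 each). For the genes higher at all 3 stages the real assignment gave 1010 and the highest of the other draws 994 (1 of 100 gave as many). Nothing is concluded from that, since the draw with 994 kept all 4 body arrays together and the others gave 0. For the groups of whole-body arrays too, only the real split called as many genes (8474 against 6210, 1 of 35).

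Some genes had 1 of the 4 whole-body arrays of the lens series far from the other arrays, measured as the gap to the nearest array over the whole range. Of 299 genes looked at, 19 stood out in this way, and chance gives about 1 in 20. Replicate 3 was lowest for Epcam (0.887), Kdm5d (0.963), Lef1 (0.854), Sostdc1 (0.860), Sox2 (0.902) and Tfap2a (0.954), and highest for Cryba2 (0.886), Lss (0.908) and Mki67 (0.882). Replicate 1 was lowest for Barx1 (0.832), Ier2 (0.915) and Plvap (0.846). Replicate 2 was highest for Hes1 (0.877) and Jag1 (0.899) and lowest for Wnt10a (1). Replicate 4 was highest for Nefl (0.877), Postn (0.886) and Tie1 (0.955) and lowest for Mcm5 (0.845). Sox2, for example, read 9.22 on replicate 3 and 10.09 to 10.18 on the others.

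Probe sets that name no gene in the annotation also differed. Of 3038 such probe sets that pass the filter, 174 were at least 2-fold higher in lens than in the body at all 3 stages and 323 at least 2-fold higher in tooth germ.

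E10.5 lens replicate 3 carried crystallin and fibre transcripts far above the other E10.5 arrays: 13.46 against 3.96 for Crygb, 13.56 against 5.41 for Cryba4 and 10.66 against 5.48 for Bfsp1, but 6.88 against 6.30 for Bfsp2. The tables argue against E12.5 lens RNA mixed into the sample, since the 6 of 22 listed transcripts below the ceiling imply shares from 3.80% to 235%, a ratio of 61.7. On replicate 3, 394 other genes higher at E12.5 than at E11.5 had a median step of 0.33, and 459 lower ones of -0.10. These medians do not argue against added lens RNA, so the argument rests on the listed transcripts. Above every E12.5 array lay 4 of the 22. Of the 22, 15 lay above every E11.5 array and 2 below every one. Some of the 15 did so by little near the ceiling (Cryba1, 14.25 against at most 14.14), others by more below it (Bfsp1, 10.66 against at most 7.205). With that limit the tables argue against collection between E10.5 and E11.5. They argue against the hybridisation set as the whole source, since the 6 transcripts differed by a median of 0.019 between the sets at E12.5 where their step on replicate 3 was 2.10, although all 22 differed by 0.89 at E11.5. RNA of a lens older than E12.5 stays open and was not tested, and no biological explanation other than stage was tested.

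Tooth germ replicate 3 carried crystallin transcripts more than 2-fold above the mean of the other tooth arrays for 9 of 14 crystallins, for example 8.88 against 4.85 for Cryba1 and 9.50 against 6.52 for Crygf. Lens RNA in the sample cannot be told apart from other sources: the median implied share, 0.782%, would put Cryaa at 7.64 where 4.42 was measured. In the whole-body arrays Cryaa also lay below the level implied there (5.21 against 6.13), but the labels do not say whether these bodies kept their eyes. The shares take the lens profile from arrays of the other series, so these values exclude nothing. The tables argue against an exchange with a whole-body array, since over 27 dental and epithelial genes replicate 3 lay at a median of 99.6% of the way from body to the other tooth arrays (single genes from 3.27% to 167%). These genes were called with replicate 3 in the group; over the 26 called without it the median was 99.1%. Replicate 3 also stood apart from the other tooth arrays in Xist and the Y-linked gene Eif2s3y, with values given under other observations. Those values argue against the same sex of embryos on all 3 tooth germ arrays. No biological explanation of the crystallin signal was tested.

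The whole-body groups of the 2 series differed for 8474 genes, the most of the 9 comparisons. Of genes with at least 2 called probe sets, 53.2% had probe sets called in opposite directions, against at most 23.0% in comparisons within a series. That is consistent with probe sets that respond differently in the 2 series, whose Gapdh 5' to 3' ratios were 0.964 to 1.07 and 0.0590 to 0.142. The bodies also differ in embryonic age, E10.5 to E12.5 and E11.5 to E13.5, which stays open as untested. Xist differed between them as well, so a different sex of the embryos stays open too.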

How the results depend on the processing

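Most results kept their side of the threshold, and few called ones changed sign. Of 455 counts of genes under the alternatives, 372 stayed within 1.5 times the reported count and 83 moved beyond it. Of 5841 list values, 5555 counted as unchanged, 131 lost the call, 146 gained one and 9 changed sign. Of 25226 values of named genes, 23912 counted as unchanged, 1141 lost the call, 76 gained one and 97 changed sign. Values called neither in the main fit nor in the alternative count as unchanged whatever their sign. A value that was called in either and changed sign is counted only as such, also where its call was lost. The division by bacterial control signal and the fits on the arrays of 1 series were chosen after the data were seen; the other settings were planned and all of them were run, except that a setting gives no value where it leaves no array or no probe set. No count moved beyond 1.5 times with the mean of a gene's probe sets, without probe sets of the _s_at and _x_at kinds, without a filter, with quantile normalization, with median centring, with the intensity trend, with all whole-body arrays as the control, or with 1 series alone. Camera with an estimated correlation ended 54 list calls, and fry ended 3 and added 67. The smallest changes are limited by signal over background: control probe sets with no target reached 4.71 at the 95th percentile and genes entered above 5.46. Where a setting below changes a result, the cause was not tested unless the setting itself tests more probe sets, applies a stricter threshold or uses fewer arrays.

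The replicate block changed no count beyond 1.5 times. It ended 31 calls of named genes, among them Btg2, Smad6, Dkk1 and Aldoa for E12.5 against E11.5 and Pax9 in tooth germ, and added 1, Cryba1 for E12.5 against E10.5. It ended 1 list call, cell division in E11.5 lens against body, and changed no other. That call (camera adjusted p = 0.0478) had an adjusted p = 0.462 with an estimated correlation.

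With every probe set tested, which tests more features, the counts were 4628 higher and 4305 lower (E10.5 lens against body), 4572 higher and 4837 lower (E11.5 lens against body), 4962 higher and 5899 lower (E12.5 lens against body), 318 higher and 641 lower (E11.5 against E10.5) and 653 higher (E12.5 against E11.5). There were also 2165 higher and 3533 lower (E12.5 against E10.5), 4712 higher and 6026 lower (tooth germ against body), 5108 higher and 4786 lower (lens minus tooth enrichment), 8773 higher and 9602 lower (tooth-series against lens-series bodies) and 2556 (all 3 stages). With the stricter filter the count was 1656 lower (E10.5 lens against body). With a fold of at least 2 required they were 486 higher and 1347 lower (E10.5 lens against body), 528 higher and 1405 lower (E11.5 lens against body), 763 higher and 1667 lower (E12.5 lens against body), 74 higher and 133 lower (E11.5 against E10.5) and 199 higher and 85 lower (E12.5 against E11.5). There were also 468 higher and 553 lower (E12.5 against E10.5), 523 higher and 1386 lower (tooth germ against body), 1539 higher and 1603 lower (lens minus tooth enrichment) and 1986 higher and 2051 lower (tooth-series against lens-series bodies). At an adjusted p under 0.01 they were 1138 higher (E10.5 lens against body), 1247 higher (E11.5 lens against body), 80 higher and 156 lower (E11.5 against E10.5), 197 higher and 199 lower (E12.5 against E11.5) and 736 higher and 1136 lower (E12.5 against E10.5). There were also 1419 higher (tooth germ against body). With at least 2-fold at each stage the count was 296 (all 3 stages).

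With the groups compared alone, which uses fewer arrays, the counts were 9 higher and 47 lower (E11.5 against E10.5) and 76 higher and 63 lower (E12.5 against E11.5). With array weights they were 3333 higher (E11.5 lens against body), 1581 higher and 1600 lower (E11.5 against E10.5), 1494 higher and 2278 lower (E12.5 against E11.5) and 1880 higher (E12.5 against E10.5). The weights did not settle: E11.5 replicate 3 received 19.5 and E11.5 replicate 1 received 0.139. Directly against tooth germ, without body arrays, they were 4449 higher and 4405 lower (lens minus tooth enrichment), where tissue and series cannot be told apart. With the bacterial control set as a block the count was 568 lower (E11.5 against E10.5). Among the arrays with high bacterial control signal they were 1445 higher (E12.5 lens against body), 382 higher and 1091 lower (E11.5 against E10.5), 71 lower (E12.5 against E11.5), 672 higher and 896 lower (E12.5 against E10.5) and 512 (all 3 stages). Among those with low signal they were 1196 higher (E10.5 lens against body), 51 higher and 71 lower (E11.5 against E10.5) and 759 higher and 1079 lower (E12.5 against E10.5).

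With each array left out in turn, the counts with at least 1 value beyond 1.5 times ran from 71 to 392 higher (E11.5 against E10.5), from 136 to 408 lower (E11.5 against E10.5), from 233 to 567 higher (E12.5 against E11.5) and from 209 to 537 lower (E12.5 against E11.5). The extremes came from E10.5 replicate 2 (71 and 136), E11.5 replicate 1 (392), E10.5 replicate 3 (408), E12.5 replicate 3 (233 and 209), E11.5 replicate 2 (567) and, for 537, E11.5 replicate 1; 408, 567 and 537 themselves stayed within 1.5 times. For E11.5 against E10.5, Bfsp1 ran from -1.25 (without E10.5 replicate 2) to 1.35 (without E10.5 replicate 3) and the dental mesenchyme list from -0.015 (without E10.5 replicate 3) to 0.17 (without E10.5 replicate 1).

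Values that changed sign and were called in the main fit or in the alternative are given as log2 differences. With the mean of a gene's probe sets, which averages probe sets that can differ, these were as follows. For E11.5 lens against body: Meis1 0.043. For E12.5 against E10.5: Lss 0.17. For tooth germ against body: Mcm7 -0.024. For lens minus tooth enrichment: Fyco1 0.25 and Hoxd13 -0.52. For tooth-series against lens-series bodies: Pax6 -0.20, Maf 0.082, Gja1 -0.66, Prrx1 -0.15, Csf1r -0.053, Dcx -1.12, Hoxa5 -0.40, Hoxd13 -0.048, Axin2 -0.14, Spred1 -0.054, Lamb1 -0.71, Nid1 -0.52, Rps18 -0.052, Cryab -0.63 and Pax9 0.14. Without probe sets of the _s_at and _x_at kinds another probe set stands for the gene. For E12.5 lens against body: Lss 0.31. For E12.5 against E10.5: Lss 0.87. For tooth germ against body: Mcm7 -0.72 and Notch3 -0.31. For lens minus tooth enrichment: Mcm5 0.42. For tooth-series against lens-series bodies: Ajap1 -1.22, Dlk1 0.89, Meis2 -0.59, Gja1 -0.37, Lss -0.34, Hoxa5 -2.10, Lamb1 -0.64, Rps9 0.93 and Rps24 0.40.

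With all whole-body arrays as the control, which joins 2 series, other signs changed. For E10.5 lens against body: Pecam1 0.78, Ptprc -0.15, Btg2 0.39, Klf6 0.16 and Uty 0.18. For E11.5 lens against body: Esam 0.15, Pecam1 0.81, Mcm5 0.061, Btg2 0.64, Id1 0.69 and the list cell division 0.081. For E12.5 lens against body: Pecam1 0.75, Esam 0.26, Id1 0.69, Notum 0.038, Klf6 0.19 and Ier2 0.18. For tooth germ against body: Birc5 -0.38, Mcm7 -0.093, Fgfr1 -0.048, Id3 -0.43, Lamc1 -0.018, Pfkl -0.77, Aldoa -0.58, Pgk1 0.082, Rps24 -0.32, Rps19 -0.46, Rpl4 -0.17, Uty -0.50 and the list cytosolic ribosomal proteins -0.079. With E11.5 in place of E12.5 lens, fewer did. For lens minus tooth enrichment: Klf1 0.052, Id2 -0.043 and the list cell division 0.0069. Directly against tooth germ the body arrays no longer enter, and tissue and series cannot be told apart. For lens minus tooth enrichment: Alx1 -0.66, Epor 0.00049, Klf1 0.84, Flt1 -0.034, Ptprc -1.03, Myog 0.31, Actc1 0.084, Ttn -0.50, Fga 0.095, Apoa2 0.062, Apoa1 0.74, Tubb3 0.30, Col2a1 0.78, Matn4 0.76, Sox5 0.25, Hoxc6 0.25, Hoxb5 -0.29, Hoxd10 -0.29, Hoxd13 -0.40, Id3 1.32, Id1 2.73, Hes5 -0.71, Lama5 0.51, Aldoa 1.65, Rps24 1.44, Rps19 1.61, Rps6 -0.68, Uty 1.04 and the list liver 0.16.

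Among the arrays with high bacterial control signal, with a lone array at E11.5 and at E12.5 that is assumed to vary like the other groups, a pair of genes changed sign. For E11.5 lens against body: Agrn 0.014. For E11.5 against E10.5: Bfsp1 1.01. Among those with low signal, which hold E10.5 replicate 3 as the lone E10.5 array, more values did. For E11.5 against E10.5: the list lens crystallins -0.97, the list lens fibre membrane and cytoskeleton -0.098, the list cataract-linked genes other than crystallins -0.069 and the list dental epithelium -0.12. For E12.5 against E10.5: Crygb -0.27 and Bfsp1 -1.06.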

Other observations

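No test of an explanation is reported in this part; the values were chosen after they were seen, except those of the gene lists. Among the Wnt signalling genes, 4 of 11 were higher and 4 lower in E12.5 lens than in the body (4 and 5 adjusted over the list alone; median 0.08, camera adjusted p = 0.403, not called). Dkk3, a secreted protein of the Dickkopf family, was 4.35 ± 0.18 higher and Sfrp1, a secreted Wnt antagonist, 2.56 ± 0.20, while Wif1, another Wnt antagonist, was lower (-2.97 ± 0.21). Of 12 Notch signalling genes 3 were higher and 4 lower (4 and 4 adjusted over the list alone; median -0.29, adjusted p = 0.721, not called). The ligand Jag1 exceeded the body by 2.74 ± 0.15, and the ligands Dll1 (-2.60 ± 0.22) and Dll3 (-3.22 ± 0.17) were lower. Of 9 BMP signalling genes 1 was higher and 4 lower (1 and 4 adjusted over the list alone; median -0.23, adjusted p = 0.451, not called), with Id4, a target of BMP signals, at -4.11 ± 0.45.

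Of 8 neural retina progenitor genes 3 were higher and 3 lower in E12.5 lens (3 and 4 adjusted over the list alone; median -0.36, adjusted p = 0.517, not called). Six6, an eye field factor, was 1.62 ± 0.26 higher, and Isl1, a factor of retinal and motor neurons, was lower (-3.22 ± 0.24). Of 10 immediate early and heat shock genes 2 were higher and 3 lower (2 and 3 adjusted over the list alone; median -0.14, adjusted p = 0.760, not called): Egr1, a growth factor response gene, was 0.93 ± 0.15 higher and Klf4 lower (-2.19 ± 0.29). Of 4 sex chromosome genes 1 was higher and none lower (the same adjusted over the list alone; median -0.32, adjusted p = 0.721, not called). Xist read 10.15 to 11.49 in lens and 5.70 to 6.26 in the whole body of the lens series, and the Y-linked gene Eif2s3y was measured in all of these arrays. Xist thus parted every lens array from every body array. A difference in the sex of the embryos cannot be told apart from the tissue there, and was not tested. In the tooth series Xist read 12.89, 13.07 and 6.20 in tooth germ replicates 1, 2 and 3 and 13.11 to 13.23 in the body. Eif2s3y read 3.14, 3.51 and 8.57 in the same tooth germ arrays. Eif2s3y thus lay below the 4.71 of control probe sets on replicates 1 and 2. On replicate 3 it lay above that level, and Xist was low. These values argue against the same sex of embryos on all 3 tooth germ arrays, though no test of sex was run.

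In some lists the median, the mean and the direction of the camera test differed in sign, none of them called. At E10.5 against the body these were surface ectoderm, Wnt signalling and sex chromosome genes, at E11.5 FGF signalling and sex chromosome genes, and at E12.5 these and glycolysis. For E11.5 against E10.5 they were cartilage, dental epithelium and BMP signalling. For E12.5 against E11.5 they were muscle, neurons, Hox genes, dental epithelium, liver, Wnt signalling, basement membrane and ribosomal proteins. For E12.5 against E10.5 they were pigment, mesenchyme, endothelium, liver, cartilage, dental epithelium and BMP signalling. For tooth germ they were crystallins, fibre genes and mesenchyme, for lens minus tooth enrichment sex chromosome genes, and between the bodies fibre genes and surface ectoderm.

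Other probe sets of named genes went against the one that stands for the gene, for many genes between the bodies and for a few in the other comparisons. Between the bodies, for example, Pax6 was at 1.34 and by another probe set at -2.10. Gja1 was at 0.51 and -5.61 there, and Prrx1 at 0.94 and -2.65. Rufy3 had another probe set at 1.66, 2.10 and 2.81 in lens at the 3 stages, Top2a at 0.44 at E12.5, Mcm7 at -0.72 in tooth germ, and Hoxd13 at -2.24 and Fyco1 at 1.30 for lens minus tooth enrichment.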
